A study of Homo sapiens with 7 samples.

How the data were processed

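Messenger RNA was sequenced from RS4;11, an established human leukemia line of early B-cell type in which KMT2A (also called MLL) is joined to AFF1. The deposited data are 2 tables of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene. They were computed by the authors and identified by Entrez gene number. The exosome table holds 22017 genes in 5 libraries. They are 1 from untreated cells, 2 from cells given Nexo (exosomes released by untreated RS4;11 cells) and 2 from cells given Rexo (exosomes released by cells treated with a proteasome inhibitor). Per the labels, exosomes were given at 5 µg/ml for 4 days. The bortezomib table holds 21494 genes, after 1 entry without a gene identifier was left out, in 1 library from cells given DMSO and 1 from cells given bortezomib, which blocks the proteasome. The labels describe tolerant cells raised from 1 nM bortezomib by 1 nM every 3 days for at least 4 weeks, without stating that the bortezomib library comes from them. One protocol text says that the cells given exosomes, or saline as control, were tolerant cells, whereas the control library is labelled untreated, so which cells received the exosomes is not settled by the labels.

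The submitters' processing notes name HISAT2, Bowtie2 and RSEM and the builds hg19 and hg38. Versions, strandedness and which build belongs to which table are not given in the sources used here, and no coordinates are reported for that reason. Read counts were not used here. Low FPKM values multiplied by transcript length fell on evenly spaced steps, which gave an estimated 22250000 to 23000000 fragments per library in the exosome table and 10000000 in each library of the bortezomib table. Between 60 and 72.9% of these values lay within 0.2 of a whole fragment. Values moved by random amounts never gave as clear a spacing (concentration of at most 0.255, against 0.302 to 0.518 in the data). The estimates cover counting only and were not used as counts in any statistical test. The fragments expected at the HOXA genes, given below, rest on them. FPKM totals were 496982 to 514246 in the exosome table and 481029 to 495968 in the bortezomib table.

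Values were analysed as log2(FPKM + 1). In the exosome table, the 11181 genes with an FPKM of at least 1 in at least 2 libraries were fitted with limma 3.58.1 under R 4.3.3, with 1 coefficient per group, an intensity trend and empirical Bayes moderation (2 residual degrees of freedom, 4.54 prior degrees of freedom). The moderated test was two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The untreated group has 1 library, which was assumed to vary like the exosome groups. On simulated data with the fitted spread, the fit of Rexo against Nexo recovered 36.4% of genes changed 1.2-fold, 95.2% at 1.5-fold and 99.6% at 2-fold, with a mean of 8.4 false calls in each simulated set. The changed genes had a mean FPKM above about 5, and the simulated noise was independent, with no trend on GC content. These rates therefore need not hold for the data. The labels do not say that libraries came from separate cultures, so limma p-values per gene measure only the spread between these samples.

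Gene lists for stress responses, protein degradation, cell cycle, metabolism, lineage, signalling and RNA quality were written down before the data were examined, as were the tests, the thresholds and the first set of alternatives. Lists with at least 5 tested genes were tested with camera from limma, with a preset inter-gene correlation of 0.01. This compares the genes of a list with the other genes. Its p-values therefore rest on the spread between genes and do not measure the spread between libraries or cultures. The test was repeated with a correlation estimated for each list. That version uses only the 2 residual degrees of freedom, so almost no list could pass it. It therefore leaves undecided whether correlation between genes accounts for a call. Both were adjusted over the lists of a contrast. For members of a list, p was also adjusted over the list alone. The contrasts of Nexo and of Rexo with the untreated library share that library, and their similarity was set beside 100 simulated sets with no effect of either exosome.

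The DMSO and bortezomib libraries have no replicates, so no p-value was computed for them and no replicate check was possible. Genes were listed as different at a ratio of at least 2-fold, on values with 1 added, with an FPKM of at least 5 in the higher library. Each list with at least 5 genes at an FPKM of 1 or more in either library was ranked by its median log2 ratio among 10000 random lists of the same size matched on level in 20 bins. Of 200 unchanged simulated lists, 2.5% fell outside the middle 95% of random lists, and 100% of lists moved by 0.5 on the log2 scale were above it. The simulated ratios were shuffled over genes, so they held no shared regulation within a list and no dependence on level. The shift of 0.5 was also larger than the median of every list found outside the range except growth factor feedback. The percentiles therefore need not be calibrated for lists of genes regulated together.

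Named genes were taken by a rule. For each exosome contrast it took the 10 largest changes in each direction past the threshold, with a mean FPKM of at least 5 in a group and no overlap between the libraries of both groups. Missing places were filled by the smallest unadjusted p. For bortezomib, the rule took the 12 largest ratios in each direction. It also took members of the lists, the bortezomib target PSMB5, the joined genes KMT2A and AFF1, and the reference genes ACTB, GAPDH and B2M. RNU6-2 and RNU6-9, whose copies are identical, were left out.

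Alternatives were other pseudocounts, filters, scalings and moderation, the replicate number as a block, and leaving out each exosome library in turn. Corrections for GC content and transcript length, by removing a smooth trend from each library, and a fit on protein-coding genes alone were added after the data were seen. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.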

Results

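The data comprised messenger RNA levels in 7 libraries of RS4;11 cells, in FPKM per gene. The exosome table held 1 untreated, 2 Nexo and 2 Rexo libraries, and the bortezomib table held 1 DMSO and 1 bortezomib library. The estimated depth was 22250000 to 23000000 fragments in the exosome libraries and 10000000 in the other pair, so low values in the bortezomib table rest on fewer fragments. Between 11000 and 11044 genes had an FPKM of at least 1 in each exosome library. Pearson's r across genes between these libraries lay between 0.9916 and 0.9957. The first principal component (40.8% of the variance) placed the Nexo libraries at -11.09 and -5.61, the untreated library at -2.39 and the Rexo libraries at 6.44 and 12.65.

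The comparison of Rexo with Nexo asks what exosomes from proteasome inhibitor-treated cells do beyond exosomes as such. Only this comparison has replicates in both groups (n = 2 each). CD82 (Entrez gene 3732), a tetraspanin of the cell surface and of exosomes, was 2.12-fold higher after Rexo (log2 fold change 1.08 ± 0.085 SE, limma adjusted p = 0.026). It went from 2.79 and 2.36 FPKM in the Nexo libraries to 6.44 and 6.67 in the Rexo libraries, against 2.59 in the untreated library. ALOX5AP, which hands arachidonic acid to the leukotriene pathway, rose 2.04-fold (1.03 ± 0.173, adjusted p = 0.0485), but did not pass with a pseudocount of 0.1 (0.0511), quantile normalization (0.062), robust moderation (0.115) or a GC trend removed (0.075). Its adjusted p ranged from 0.0028 to 0.404 over all alternatives. LSP1, an actin-binding protein of leukocytes, rose 1.73-fold (0.79 ± 0.073, adjusted p = 0.027). LRRCC1, a centrosome protein, fell by 0.70 (± 0.094 SE, adjusted p = 0.0438). The condensin subunit SMC2 fell by 0.60, the kinesin KIF18A by 0.60 and the spindle proteins DLGAP5 and HMMR by 0.55 and 0.54 on the log2 scale. LRRCC1, SMC2 and KIF18A did not pass with a GC trend removed (limma adjusted p = 0.0636, 0.0556 and 0.0657) or after quantile normalization (0.0558 each). Of these alternatives HMMR missed only the GC correction (0.0556), and CD82, LSP1 and DLGAP5 passed both.

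In all, 192 of 11181 genes passed, 75 higher and 117 lower, with a median change of 1.315-fold. Among the other named genes, NCF1C rose by 0.61; it is a near-identical copy of NCF1, a subunit of the phagocyte oxidase, so reads can be shared. Increases were also found for the glycolytic aldolase ALDOC at 0.59, the calcium-binding protein S100A6 at 0.54 and the calcium pump of the endoplasmic reticulum ATP2A3 at 0.54. The ATF4 target TRIB3 was at 0.53, the membrane protein EMP3 at 0.50 and the receptor GPR18 at 0.49. Those that fell were the nuclear receptor corepressor NRIP1 at -0.62, the autophagy initiation factor RB1CC1 at -0.59, the kinetochore protein CENPC at -0.54, the cohesin subunit STAG2 at -0.53 and LARP7, which binds the 7SK RNA, at -0.52. Adjusted p for these ranged from 0.027 to 0.0493, and the rule that chose them required no overlap between the Rexo and Nexo libraries. Of all 20 named genes, 13 did not pass with a GC trend removed, 12 after quantile normalization and 4 with a pseudocount of 0.1. With no filter on low values all 20 missed the threshold. The untreated library lay between the groups for 15 of the 20 named genes. These were all the genes that fell and LSP1, NCF1C, ALDOC, S100A6 and GPR18 among those that rose. DLGAP5, for example, was at 19.41 FPKM against 23.59 and 24.32 after Nexo and 16.39 and 15.69 after Rexo. S100A6 was at -0.40 after Nexo against the untreated library (log2 scale, limma adjusted p = 0.517), so its difference is not a rise over untreated alone.

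**Figure D1:**
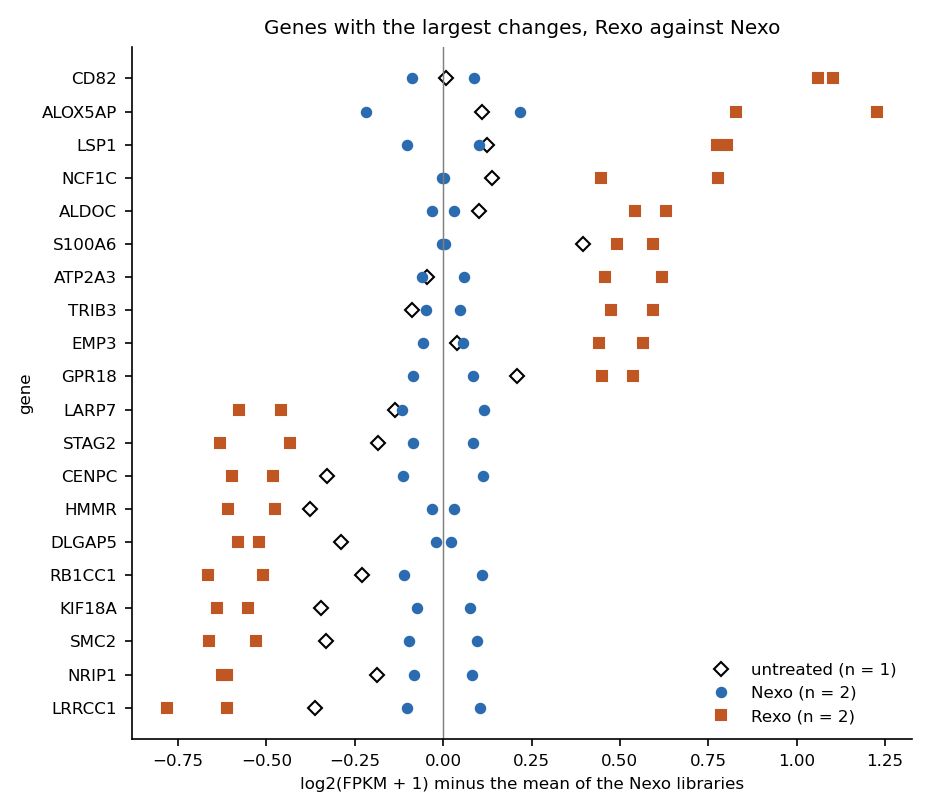
Levels of the 20 named genes in each library of the exosome table, as log2(FPKM + 1) minus the mean of the 2 Nexo libraries. Each point is 1 library (1 untreated, 2 Nexo, 2 Rexo), the genes were chosen to have no overlap between Rexo and Nexo, and CD82 lies at 2.79 and 2.36 FPKM in the Nexo libraries and 6.44 and 6.67 in the Rexo libraries.

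The test rested on all 4 exosome libraries. Of 11181 genes, limma called 0, 1, 2 and 0 genes without Nexo 1, Nexo 2, Rexo 1 and Rexo 2. Genes at an unadjusted p under 0.05 then numbered 2524, 1546, 2172 and 1360, against 2764 with all libraries. The count was 0 with no filter on low values (limma, 3152 unadjusted), 978 at an FPKM of at least 5 and 975 with robust moderation. It was 30 after quantile normalization (63.3% higher, against 39.1%), 32 after a GC content trend was removed (81.2% higher) and 1282 among protein-coding genes alone. Across 10879 genes, which are not independent replicates, the log2 change of Rexo over Nexo correlated with transcript GC content at r = 0.472. Median GC content was 59% for genes that rose, 39.4% for genes that fell and 49.5% for all.

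Mitotic genes were lower as a group after Rexo than after Nexo, with the untreated library between them. Of 31 genes of the G2/M and mitosis list, 29 were lower (median log2 change -0.14, camera adjusted p = 7.45e-09; adjusted p = 0.301 with an estimated correlation). Over all genes, 7 fell past the threshold (19 when adjusted over the list alone), among them TOP2A at -0.47, CKAP2 at -0.46, TTK at -0.44 and KIF11 at -0.38. Against the untreated library the list was at 0.13 after Nexo and at -0.02 after Rexo, where it did not pass (adjusted p = 0.175). The G1/S and DNA replication list had 26 of 29 genes lower (median -0.11, adjusted p = 2.57e-05; adjusted p = 0.419 with an estimated correlation). The 1 call was the replication checkpoint protein CLSPN at -0.34 (11 lower and 1 higher when adjusted over the list alone). Without Rexo 2 the G1/S median was -0.0669. Targets of the MLL fusion were lower in 22 of 28 genes (median -0.17, adjusted p = 3.66e-05; adjusted p = 0.419 with an estimated correlation). Of these, 4 were called (13 lower and 1 higher when adjusted over the list alone). They were MBNL1 at -0.35, CDK6 at -0.33, RUNX2 at -0.33 and ADAM10 at -0.32. HOXA9, a central target, differed by 0.00 (adjusted p = 0.987). With GC and length trends removed the medians were -0.089 for G2/M and -0.0914 for MLL fusion targets, and both lists still passed with the preset correlation.

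Cytosolic ribosomal protein genes were higher in 71 of 73 cases (median 0.12, adjusted p = 2.52e-24; adjusted p = 0.301 with an estimated correlation). RPS14 at 0.18 was the 1 call (57 when adjusted over the list alone), and the median was 0.0679 with a length trend removed. All 22 genes of cholesterol synthesis were higher (median 0.18, adjusted p = 2.65e-10; adjusted p = 0.419 with an estimated correlation). DHCR7 at 0.27 and MSMO1 at 0.26 passed (13 when adjusted over the list alone). The ATF4 target list of the integrated stress response was higher in 20 of 24 genes (median 0.13, adjusted p = 1.71e-07; adjusted p = 0.419 with an estimated correlation). Its 4 calls (12 when adjusted over the list alone) were TRIB3, the amino acid transporter chain SLC3A2 at 0.37, the growth inhibitor SESN2 at 0.36 and the tryptophan tRNA synthetase WARS at 0.32.

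The immunoproteasome and antigen presentation list had 15 of 16 genes higher (median 0.12, adjusted p = 7.25e-06; adjusted p = 0.419 with an estimated correlation). The NF-kB and inflammatory list had 14 of 17 higher (median 0.26, adjusted p = 2.57e-05; adjusted p = 0.419 with an estimated correlation). ZFP36, which destabilises inflammatory messages, was called at 0.40 (9 higher and 2 lower when adjusted over the list alone), and the list median was 0.155 without Rexo 2. Myeloid and monocytic genes were higher in 7 of 7 (median 0.28, adjusted p = 0.000218; adjusted p = 0.419 with an estimated correlation). There were 0 limma calls among them over all genes and 5 when adjusted over the list alone, with CTSG for example at 0.50 (adjusted p = 0.0706).

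Glycolysis genes were higher in 21 of 24 (median 0.06, adjusted p = 0.000825; adjusted p = 0.419 with an estimated correlation). ALDOC at 0.59 was the 1 call over all genes and when adjusted over the list alone. Camera also passed cell adhesion and matrix (median 0.12, adjusted p = 0.0076) and unfolded protein response genes of the endoplasmic reticulum (0.07, adjusted p = 0.0132), each at adjusted p = 0.419 with an estimated correlation. NRF2 targets (0.08, adjusted p = 0.0145) and nuclear oxidative phosphorylation genes (0.02, adjusted p = 0.0312) passed too, each at adjusted p = 0.419 with an estimated correlation. Calls over all genes were ITGA4 at -0.30 in the adhesion list (5 higher and 1 lower when adjusted over the list alone) and FTH1, the ferritin heavy chain, at 0.24 in the NRF2 list (3 when adjusted over the list alone). The adhesion list did not pass without Nexo 1 (adjusted p = 0.095), NRF2 targets without Nexo 1 (0.095) or Rexo 2 (0.0639). Oxidative phosphorylation did not pass without Nexo 1 (0.0794) or Rexo 2 (0.0943), nor the unfolded protein response without Rexo 1 (0.0954). Medians also moved for glycolysis without Nexo 2 (0.0397) or Rexo 2 (0.0332), and adhesion without Rexo 1 (0.191), and the glycolysis median was 0.0333 with a GC trend and 0.0218 with GC and length trends removed. Further medians that moved were NRF2 targets without Rexo 2 (0.0542), the unfolded protein response without Nexo 2 (0.0474) and oxidative phosphorylation without Rexo 1 (0.0346). The oxidative phosphorylation median was -0.01 once a length trend was removed, and the list did not pass with a GC trend removed (adjusted p = 0.108), nor did NRF2 targets with a length trend removed (median 0.0309, adjusted p = 0.0821). After quantile normalization glycolysis (adjusted p = 0.0654), the unfolded protein response (0.0696), NRF2 targets (0.206) and oxidative phosphorylation (0.829) did not pass.

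Proteasome genes did not pass as a list, with 22 of 37 lower (median -0.04, camera adjusted p = 0.15). Among them limma called 0 over all genes and 5 lower when adjusted over the list alone. PSMB5, the subunit that bortezomib binds, stood at 51.59 and 52.5 FPKM after Nexo and 52.77 and 59.46 after Rexo. The heat shock list did not pass (median 0.03, adjusted p = 0.209). HSPA1A rose by 0.54 and its near-identical copy HSPA1B by 0.43, from reads that can be shared. HSPB1 rose by 0.25, whereas HSP90AA1 fell by 0.27 (5 higher and 3 lower when adjusted over the list alone). The early B-lineage list did not pass either (adjusted p = 0.347, median -0.02 although camera's direction was up). VPREB3 at 0.45, CD79B at 0.21 and CD79A at 0.20 were called (5 higher and 4 lower when adjusted over the list alone). Median and direction also differed in sign for interferon-stimulated genes (median -0.01, direction up, adjusted p = 0.303, with BST2 called at 0.35; 3 higher and 1 lower when adjusted over the list alone). The mean differed in sign from the median for drug efflux transporters (median 0.03, mean -0.02, adjusted p = 0.887) and for nuclear-retained and long noncoding RNA (median 0.02, mean -0.12, adjusted p = 0.209). SNHG8 at 0.28 and GAS5 at 0.26 were called in that last list (4 higher and 2 lower when adjusted over the list alone).

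Adjusted p was 0.0943 for MYC targets, 0.113 for mature B and plasma cell genes, 0.15 for stem and progenitor regulators, and 0.199 for exosome biogenesis. It was 0.263 for ubiquitin and autophagy, 0.299 for replication-dependent histones, 0.484 for the BCL2 family, 0.651 for growth factor feedback and 0.887 for p53 targets. T and NK cell, erythroid and fibroblast lists had 4, 4 and 3 tested genes, too few to test. The mitochondrially encoded transcripts were absent from both tables (0 genes). None of the 14 lists that passed kept its call with an estimated correlation, a test whose 2 residual degrees of freedom let few lists pass. Their directions held after quantile normalization, where 10 of them passed, but sizes did not: the ribosomal protein median was 0.0276 in place of 0.12, that of NRF2 targets 0.0347 and that of oxidative phosphorylation 0.000306. No scaling moved the median of all genes by more than 0.1.

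**Figure D2:**
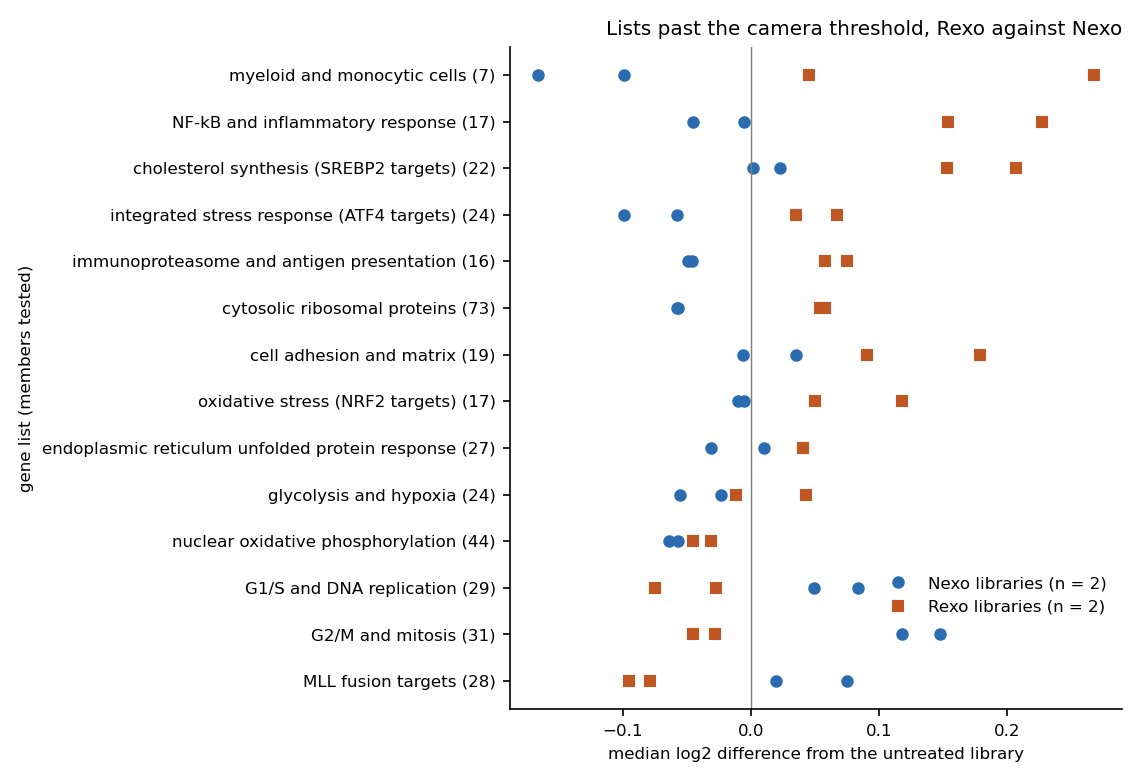
Median log2 difference of each list from the untreated library, for the 14 lists past the camera threshold between Rexo and Nexo. Each point is 1 library (2 Nexo, 2 Rexo) with the number of tested members beside each list, and the 73 ribosomal protein genes lie at -0.06 after Nexo and between 0.05 and 0.06 after Rexo.

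The comparison of Nexo (n = 2) with the untreated library (n = 1) asks what exosomes from untreated cells do. SNORD137 (Entrez gene 106635615), a small nucleolar RNA, was 4.20-fold higher, at 25.36 and 25.42 FPKM against 5.28 (log2 2.07 ± 0.07 SE, limma adjusted p = 0.000367). It was the 1 gene of 11181 that passed (730 at an unadjusted p under 0.05). It did not pass without Nexo 1 (adjusted p = 0.0814), Nexo 2 (0.112) or Rexo 2 (0.0531). Its length is not in the annotation used, so the fragments behind its levels are unknown. Genes that did not pass included HMMR at 0.38, DIAPH3 at 0.36, NDC80 at 0.32, DLGAP5 at 0.29 and NPIPB5 at 0.38. MIR4461 was at 0.32, the pseudogenes RPS14P3 and RPS18P9 at 1.92 and 1.43, and SNORA104 at 1.23 (adjusted p = 0.193 to 0.579). Negative values were found for BOLA2B at -0.48, S100A6 at -0.40, FAM96B at -0.34, and SNHG8 at -0.33. They were also found for ZFAS1 at -0.27, RPS26 at -0.26, ATP5J2 at -0.23, MYL6 at -0.22, NDUFB2 at -0.22 and RPLP1 at -0.20 (adjusted p = 0.193 to 0.569).

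As groups, mitotic genes were higher in the Nexo libraries than in the untreated library, in 30 of 31 cases (median 0.13, camera adjusted p = 1.64e-13; adjusted p = 0.321 with an estimated correlation). Members called by limma were 0 over all genes and 7 when adjusted over the list alone. G1/S genes were higher in 25 of 29 (median 0.06, adjusted p = 0.000386; adjusted p = 0.544 with an estimated correlation). MLL fusion targets were higher in 21 of 28 (median 0.05, adjusted p = 0.0336; adjusted p = 0.836 with an estimated correlation). Ribosomal protein genes were lower in 61 of 73 (median -0.05, adjusted p = 3.61e-11; adjusted p = 0.321 with an estimated correlation), with 0 limma calls over all genes and 4 when adjusted over the list alone. With a length trend removed this list did not pass (median -0.0176, adjusted p = 0.127). Lower values were also found for 36 of 44 oxidative phosphorylation genes (median -0.06, adjusted p = 1.16e-07; adjusted p = 0.321 with an estimated correlation). Heat shock genes were lower in 20 of 22 (median -0.07, adjusted p = 3.81e-07; adjusted p = 0.321 with an estimated correlation). ATF4 targets were lower in 21 of 24 (median -0.08, adjusted p = 7.47e-05; adjusted p = 0.501 with an estimated correlation). The list of nuclear-retained and long noncoding RNA, included as a possible sign of RNA quality, was lower in 10 of 12 (median -0.13, adjusted p = 0.000845; adjusted p = 0.345 with an estimated correlation; 1 call when adjusted over the list alone). This list thus differed in the same contrast as the groups above. It also holds host genes of small nucleolar RNAs, such as SNHG8 and GAS5, so its shift need not reflect RNA quality. With 1 untreated library, the deviation of that library itself cannot be separated from an effect of the exosomes, here or after Rexo.

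The remaining 5 lists that passed were lower, starting with MYC targets (median -0.04, adjusted p = 0.0236; adjusted p = 0.501 with an estimated correlation). Myeloid genes followed (-0.13, adjusted p = 0.024; adjusted p = 0.781 with an estimated correlation), then immunoproteasome genes (-0.05, adjusted p = 0.0336; adjusted p = 0.781 with an estimated correlation). The last were glycolysis (-0.04, adjusted p = 0.0466; adjusted p = 0.836 with an estimated correlation) and histones (-0.15, adjusted p = 0.0466; adjusted p = 0.501 with an estimated correlation). Without Nexo 2, 8 of the 13 lists passed. Then MYC targets (adjusted p = 0.05), myeloid (0.142), immunoproteasome (0.078), glycolysis (0.412) and MLL fusion targets (0.642) did not. Immunoproteasome genes (0.0526) and histones (0.0857) also missed without Nexo 1, where the median was -0.0552 for histones, -0.117 for heat shock and 0.0751 for MLL fusion targets. Without Nexo 2 it was -0.0229 for glycolysis and 0.0196 for MLL fusion targets. Histones (0.0826 and 0.0831) and MLL fusion targets (0.0566 each) missed without Rexo 1 or Rexo 2. After quantile normalization ribosomal proteins (adjusted p = 0.0833), immunoproteasome genes (0.592), MYC targets (0.406) and glycolysis (0.587) did not pass, and the oxidative phosphorylation median was -0.0356. Median and direction differed in sign for p53 targets (median 0.02, direction down, adjusted p = 0.944), interferon-stimulated genes (0.01, down, adjusted p = 0.755). They also differed for exosome biogenesis (0.00, down, adjusted p = 0.625) and mature B and plasma cell genes (0.02, down, adjusted p = 0.755).

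The comparison of Rexo (n = 2) with the untreated library (n = 1) asks for the whole effect of exosomes from inhibitor-treated cells. SNORD137 was again the 1 gene that passed, at 23.15 and 21.05 FPKM against 5.28 (log2 1.88 ± 0.07 SE, limma adjusted p = 0.000693; 1283 genes at an unadjusted p under 0.05). It did not pass without Nexo 1 (adjusted p = 0.052), Nexo 2 (0.0567), Rexo 1 (0.0783) or Rexo 2 (0.0834). CD82 stood at 1.07, LSP1 at 0.66, TRIB3 at 0.62, ATP2A3 at 0.58 and ALDOC at 0.49. AIF1 was at 0.43, HVCN1 at 0.38, VPREB3 at 0.38 and RPS14P3 at 1.78, none past the threshold (adjusted p = 0.156 to 0.227). Negative values were found for CMTM1 at -0.50, LOC441454 at -0.45, CEBPZ at -0.42, BOLA2B at -0.34, HSP90AA1 at -0.29 and TOP2A at -0.25. The short or pseudogene transcripts were RPL21P28 at -2.14 and MIR5047 at -1.41 (adjusted p = 0.232 to 0.278).

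Cholesterol synthesis had the smallest adjusted p among lists after Rexo, higher in 21 of 22 genes (median 0.18, camera adjusted p = 2.48e-13; adjusted p = 0.495 with an estimated correlation). Its members had 0 limma calls over all genes and 12 when adjusted over the list alone. NF-kB and inflammatory genes were higher in 14 of 17 (median 0.19, adjusted p = 0.000113; adjusted p = 0.495 with an estimated correlation). Ribosomal proteins were higher in 58 of 73 (0.06, adjusted p = 3.88e-09; adjusted p = 0.495 with an estimated correlation). Adhesion genes were higher in 16 of 19 (0.14, adjusted p = 0.000441; adjusted p = 0.495 with an estimated correlation). Immunoproteasome genes (0.07, adjusted p = 0.000441) and ATF4 targets (0.05, adjusted p = 0.00203) were higher, each at adjusted p = 0.495 with an estimated correlation. NRF2 targets (0.06, adjusted p = 0.0102) and the unfolded protein response (0.05, adjusted p = 0.0158) were higher, each at adjusted p = 0.495 with an estimated correlation. So were myeloid genes (0.08, adjusted p = 0.0181; adjusted p = 0.559 with an estimated correlation). All 28 MYC targets were lower (median -0.07, adjusted p = 3.9e-05), as were 24 of 28 MLL fusion targets (-0.11, adjusted p = 0.00151), each at adjusted p = 0.495 with an estimated correlation. Lower too were 30 of 37 proteasome genes (-0.04, adjusted p = 0.00256) and 32 of 44 oxidative phosphorylation genes (-0.05, adjusted p = 0.0253), each at adjusted p = 0.495 with an estimated correlation. Neither cell cycle list passed, with 17 of 31 G2/M genes lower (median -0.02, adjusted p = 0.175) and 20 of 29 G1/S genes lower (-0.06, adjusted p = 0.0607).

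Without Rexo 1, the proteasome list (adjusted p = 0.0524), the unfolded protein response (0.105) and oxidative phosphorylation (0.138) did not pass. Without Rexo 2, NRF2 targets (0.077) and myeloid genes (0.173) did not, nor did ribosomal proteins after quantile normalization (0.15). The myeloid median rested on Rexo 2, at 0.268 without Rexo 1 and 0.0453 without Rexo 2. Other medians that moved were those of NRF2 targets (0.118) and oxidative phosphorylation (-0.0306) without Rexo 1, and of the proteasome (-0.0646) and adhesion (0.0909) without Rexo 2. Median and direction differed in sign for exosome biogenesis (median 0.00, direction up, adjusted p = 0.347) and early B-lineage genes (median -0.01, direction up, adjusted p = 0.478). Because Nexo and Rexo were set against the same library, their log2 changes correlate by construction. Across genes r was 0.509, against 0.666 (SD 0.02) in 100 simulated sets with no effect. In the data 56.6% of genes shared a sign, against 73.3% simulated. The covariance was 0.0156 against 0.00811 simulated, an excess of 0.00748. The shared call was 1, SNORD137, with 8.9e-05 expected for independent calls. The single control cannot be divided between the contrasts, so part of this excess and the shared SNORD137 call may come from that library itself.

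The comparison of bortezomib with DMSO asks how the cells differ under proteasome inhibition, with 1 library on each side and no replicate check. The homeobox gene HOXA9 (Entrez gene 3205), which the MLL fusion drives, stood at 63.95 FPKM with DMSO and was listed at 0 with bortezomib. HOXA7 (41.08), HOXA10-AS (25.32) and HOXA-AS3 (17.12) were also listed at 0, and HOXA10 was at 23.33 and 0.09 (log2 ratio -4.48). DNTT, the polymerase of antigen receptor joining, stood at 136.6 and 4.35 FPKM (-4.68), and the B-cell adaptor BLNK at 60.5 and 1.63 (-4.55). The cytokine signalling inhibitor SOCS2 was at 180.37 and 2.56 (-5.67), the growth factor MDK at 159.91 and 2.05 (-5.72) and CRIP1 at 64.43 and 0.23 (-5.73). RAB34 stood at 51.5 and 0.09 (-5.59) and the adhesion molecule PECAM1 at 21.47 and 0.38 (-4.03).

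Higher with bortezomib were the vesicle fusion protein VAMP8, from 0.80 to 48.89 FPKM (log2 ratio 4.79), and the B-cell scaffold BANK1, from 0.41 to 32.56 (4.57). So were the Notch modifier MFNG, from 0.53 to 27.03 (4.20), the class II antigen HLA-DQA1, from 0.07 to 18.3 (4.17), and the membrane glycoprotein GPM6B, from 1.08 to 25.25 (3.66). SNORD58B (27.66), SNORA100 (26.88), MIR378I, SNORD50B, SNORD59A and SNORD14C were listed at 0 with DMSO, and SNORD86 stood at 2.40 and 70.36. Such short transcripts made up 59 of the 333 genes at least 2-fold higher and 22 of the 233 at least 2-fold lower, among 9151 genes with an FPKM of at least 5 (Spearman's rho 0.95 across genes). The count of 566 was 288 with a pseudocount of 5 and 1003 with a minimum FPKM of 1.

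**Figure D3:**
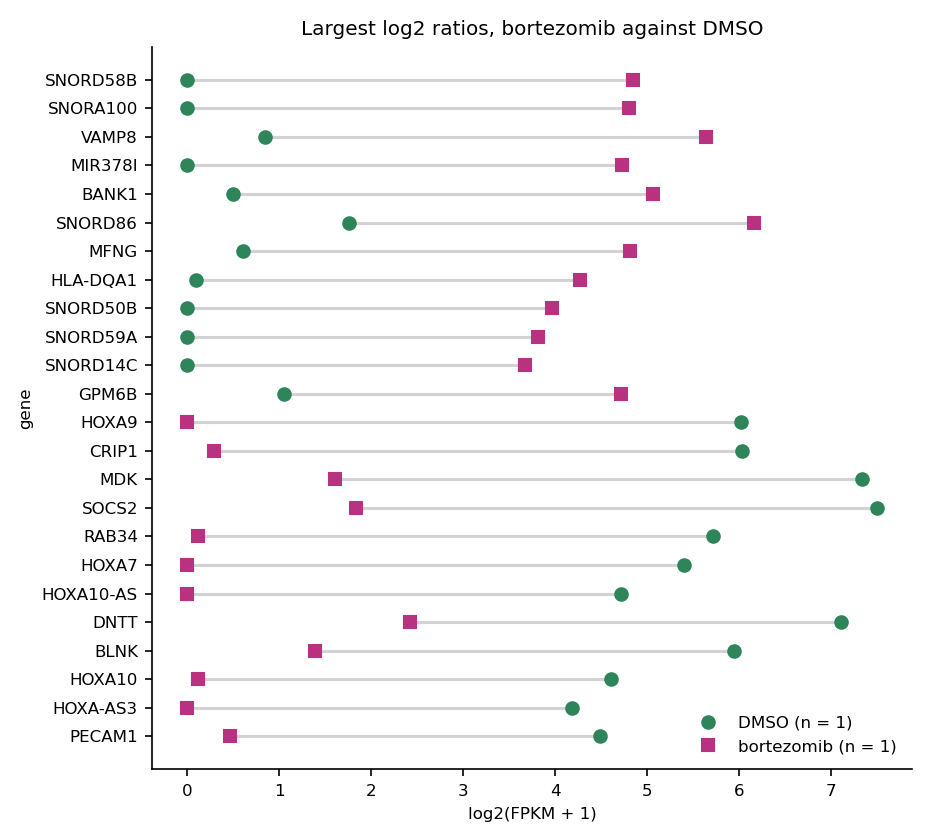
Levels of the 24 genes with the largest log2 ratios, as log2(FPKM + 1), in the DMSO library (1 library) and the bortezomib library (1 library), joined by a line. HOXA9 goes from 63.95 FPKM to 0 and VAMP8 from 0.80 to 48.89.

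Cholesterol synthesis genes stood above matched random lists, with 19 of 22 higher (median log2 ratio 0.41, percentile 100). LSS was at 23.33 and 69.35 FPKM, MSMO1 at 24.38 and 70.58 and SQLE at 133.18 and 249.99 with DMSO and bortezomib, whereas CYP51A1 was at 26.61 and 2.88. Nuclear oxidative phosphorylation genes (median 0.09, percentile 99.1, 27 of 44 higher) and early B-lineage genes (0.12, percentile 98.2) also lay above, but not among random lists unmatched on level (percentiles 79.9 and 88.3). The early B-lineage list was mixed, with 3 genes at least 2-fold higher and 4 lower, IRF4 going from 20.44 to 47.35 and IL7R from 100.62 to 41.01.

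Lists below matched random lists were MLL fusion targets (median -0.33, percentile 0, 7 of 29 at least 2-fold lower), and growth factor feedback (-0.84, percentile 0, 9 of 12 lower). The others were NF-kB (-0.22, percentile 0.22), proteasome (-0.14, percentile 0.7, 28 of 37 lower) and ATF4 targets (-0.15, percentile 1.04). The MLL targets at least 2-fold lower included HOXA5 (11.01 and 0 FPKM) and CDK6 (156.22 and 76.64), whereas MEIS1 stood at 30.70 and 29.90. Within the ATF4 list TRIB3 went from 7.28 to 19.98 and WARS from 24.63 to 67.34 while VLDLR went from 12.4 to 3.89. Within the NF-kB list IL1B went from 4.39 to 30.3 while IER2 went from 51.75 to 16.39. PSMB5 was at 51.35 and 64.09 FPKM (0.31), KMT2A at 10.42 and 6.43 (-0.62) and AFF1 at 26.73 and 9.25 (-1.44). The reference genes had log2 ratios of 0.43 for ACTB, -0.04 for GAPDH and -0.08 for B2M.

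The other lists lay inside the middle 95% of matched random lists. Among unmatched ones G1/S (percentile 1.89), ribosomal protein (0.45) and erythroid genes (1) lay below it. Percentiles were 2.89 for G1/S, 5.3 for erythroid, and 7.19 for myeloid genes. They were 7.68 for the unfolded protein response, 8.12 for fibroblast, 8.44 for G2/M, 10.7 for ribosomal protein and 12.9 for histone genes. They were 18.7 for ubiquitin and autophagy, 18.9 for the BCL2 family, and 19 for p53 targets. Values of 26.9 for T and NK cell genes, 30 for drug efflux, 31.9 for immunoproteasome and 32.8 for exosome biogenesis followed. Above the middle were glycolysis at 70.4, adhesion at 72, stem and progenitor genes at 72.3 and heat shock at 80.9. Still higher percentiles were 83.5 for interferon-stimulated genes, 84.1 for NRF2 targets, 93.5 for MYC targets, 93.6 for mature B and plasma cell genes and 96.8 for nuclear-retained RNA. That last list lay outside the middle 95% at a pseudocount of 0.1 (percentile 98.6).

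The change after Rexo relative to Nexo was set beside that under bortezomib, since Rexo come from inhibitor-treated cells. ALDOC, TRIB3, LSP1 and VPREB3 were higher in both (bortezomib log2 ratios 2.62, 1.34, 1.82 and 0.73). CD82 was at 4.25 FPKM with DMSO and 2.70 with bortezomib. Across 10915 genes Pearson's r was -0.014 (-0.017 to -0.006 over the pairs of 1 Rexo and 1 Nexo library) and Spearman's rho -0.007, with genes not being independent replicates. Of 186 genes called between Rexo and Nexo and measured in both tables, 99 (53.2%) had the same sign under bortezomib, against 48.6% of all genes. These were 44 of 70 that rose and 55 of 116 that fell. The cholesterol list was higher in both comparisons and MLL fusion targets lower in both, while ATF4 and NF-kB targets were higher after Rexo and below random lists under bortezomib. These 4 lists missed the camera threshold between Rexo and Nexo with an estimated correlation (adjusted p = 0.419 for each). With 2 residual degrees of freedom that test cannot decide their calls. These differences between tables were not tested.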

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

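The tests of a gradient within the groups, of read number at the HOXA genes and, in both its parts, of the DMSO library as the one that stands apart were chosen only after the results were seen, as were the corrections for GC content and length.

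For 10 of 29 gene lists, the medians of both Nexo libraries lay on one side of the untreated library and those of both Rexo libraries on the other. Against the untreated library, the NF-kB, NRF2 and mature B lists did not pass after Nexo. After Rexo the G2/M, G1/S and mature B lists did not, so for these lists a change to both sides was not shown. The other lists passed on both sides only with the preset correlation and against 1 untreated library. After quantile normalization ribosomal proteins passed on neither side and immunoproteasome genes did not pass after Nexo. Medians also differed between libraries, at 0.02 and 0.075 in Nexo 1 and 2 for MLL fusion targets and 0.045 and 0.268 in Rexo 1 and 2 for myeloid genes. The difference itself is the contrast of Rexo with Nexo, with camera adjusted p in brackets: cytosolic ribosomal proteins 0.118 (2.52e-24), ATF4 targets 0.127 (1.71e-07), immunoproteasome 0.122 (7.25e-06), NF-kB 0.259 (2.57e-05), myeloid genes 0.275 (0.000218), NRF2 targets 0.0844 (0.0145), G2/M -0.142 (7.45e-09), G1/S -0.105 (2.57e-05), MLL fusion targets -0.172 (3.66e-05) and mature B and plasma cell genes 0.106, which did not pass (0.113). These became adjusted p = 0.301 with an estimated correlation for ribosomal proteins and G2/M and 0.419 for the others. The G2/M list, for example, lay at 0.15 and 0.12 after Nexo and -0.03 and -0.05 after Rexo. Without Rexo 2 the difference was 0.155 for NF-kB, -0.0669 for G1/S and 0.0542 for NRF2 targets.

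The untreated library also lay between the groups for 15 of the 20 named genes, each with a limma adjusted p of at most 0.0493 between Rexo and Nexo. These genes were chosen for that p and for a gap between the groups, into which an unchanged control can easily fall. None of the 15 passed against the untreated library after Nexo or Rexo, so opposite changes were not shown. How many such genes or lists to expect without an effect was not computed. Log2 changes were 0.79 for LSP1, 0.612 for NCF1C, 0.587 for ALDOC, 0.543 for S100A6 and 0.494 for GPR18. They were -0.696 for LRRCC1, -0.618 for NRIP1, -0.596 for SMC2, -0.596 for KIF18A, -0.587 for RB1CC1, -0.551 for DLGAP5, -0.541 for HMMR, -0.539 for CENPC, -0.532 for STAG2 and -0.519 for LARP7.

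The first pattern is the 192 genes called between Rexo and Nexo, with mitotic genes lower, and removing a transcript length trend left 145 of 189 called and 91.1% of the median change, which argues against length as the whole cause; the G2/M median of -0.142 lay at percentile 0.05 of random lists matched on GC content, length and level (middle 95% from -0.104 to -0.024), although matched genes were lower too. A GC content trend fits as a partial cause: once it was removed 29 of 189 were still called, 188 had an unadjusted p under 0.05 and the median adjusted p was 0.0771. The median change went from 0.395 (SE 0.0573) to 0.288 (SE 0.048), with 70.1% of the change and all 189 signs left, and genes of the whole table at an unadjusted p under 0.05 went from 2764 to 2050; which of these ended the calls was not tested. A gradient that also runs within the groups fits as well, since the changes of the called genes correlated with the difference between the Rexo libraries (r = 0.382) and, with the opposite sign, between the Nexo libraries (r = -0.384). The GC trend itself ran within the groups across all genes with a GC value (r = -0.252 for Nexo 2 minus Nexo 1, 0.151 for Rexo 2 minus Rexo 1). It and this gradient are therefore not separate explanations. What stays open is whether that gradient may come from RNA or library preparation or from how strongly each culture responded to the exosomes, which 2 libraries per group do not show.

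The second pattern is the loss of HOXA messages in the bortezomib library. A lack of fragments is argued against, since 8 of the 8 HOXA genes at an FPKM of 0.1 or less had at least 10 fragments expected at the DMSO level (15.6 to 1317.4). These expected numbers rest on the estimated depth of 10000000 fragments. Loss of a chromosome segment reaching beyond the cluster is also argued against by the nearest expressed genes, SKAP2 at 0.811 and HIBADH at 1.58 of the DMSO level. A smaller deletion and silencing of the cluster, for which the drug or growth of a subclone is a candidate cause, stay open and untested, and 1 library shows neither.

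The third pattern is genes present in 1 of the DMSO and bortezomib libraries only (an FPKM of at least 5 against at most 0.1), 23 in number. That the DMSO library is the odd one is argued against for the genes it alone expresses. Of these 17, 16 had an FPKM of at least 1 in all 5 exosome-table libraries. The 17 include HOXA9 and other genes of the HOXA cluster, so they are not all separate cases. An FPKM of 1 is also a lower bar than the 5 used for presence. The limit of 0.1 leaves out SOCS2, DNTT and BLNK, which stood nearer bortezomib in the untreated library. Of 59 genes at least 4-fold lower with bortezomib, 39 lay nearer DMSO in all 5 exosome-table libraries and 15 nearer bortezomib. The explanation fits for 4 of the 6 genes of the bortezomib library only, which had an FPKM of at least 1 in all 5. Variation between cultures of the line cannot be told apart from the drug. DMSO and the untreated library differed by 69 such genes, more than the 23 between DMSO and bortezomib. Of the 69, 57 separated bortezomib from untreated as well, which left 12. Those 57 may mark the tables or the cultures used for each, and which of these was not tested. Among the exosome-table libraries at most 2 such genes were found for any pair. The drug, given during selection or not, may be the source but was not tested against a second pair of cultures.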

How the results depend on the processing

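Corrections for GC content and length and the fit on protein-coding genes were chosen after the data were seen. Calls between Rexo and Nexo (192) were 160, 234 and 284 with pseudocounts 0.1 and 5 and median-ratio scaling and 182 with a length trend removed. They were 0 with no filter (limma, 3152 unadjusted; 19681 genes tested), 978 at an FPKM of 5, 30 with quantile normalization and 975 with robust moderation. They were 32, 21 and 29 with GC, with GC and length, and with both and a block removed, 1282 in protein-coding genes, and 0 to 2 leaving out 1 library (1360 to 2524 unadjusted). The deviations of Nexo 1 and Rexo 1 correlated at -0.05 across genes, so the numbers showed no pairing, and a block gave 218 calls, 170 of them shared. Calls of Nexo against untreated (1) were 37 with no filter, 3 at an FPKM of 5, 9 with robust moderation and 0 to 2 leaving out 1 library (514 to 816 unadjusted). They were 0 with each trend removed (588 to 741 unadjusted) and in protein-coding genes (726), where SNORD137 is not among the genes tested. Calls of Rexo against untreated (1) were 39, 13, 12 and 0 to 1 (561 to 1190 unadjusted) in that order. They were 0 with each trend removed (1218 to 1282 unadjusted) and 11 in protein-coding genes. SNORD137 is again not among the genes tested there, so the loss of its call says nothing about it. Lists passing were 14, 13 and 13, and 0 in each contrast with estimated correlations, where 2 residual degrees of freedom let few lists pass. They were 11 to 15, 8 to 11 and 12 to 13 leaving out 1 library, and 8 for Nexo against untreated with GC, length or both trends removed. Lost there were immunoproteasome, histone and glycolysis genes and MLL fusion targets in all 3 (adjusted p from 0.0522 to 0.547), myeloid genes with GC (0.0561) or both (0.0712) removed and ribosomal proteins with length removed (0.127). Myeloid genes lost their call between Rexo and untreated with GC (0.0875) or both (0.0807) removed. The oxidative phosphorylation median between Rexo and Nexo was -0.00884 with length removed and -0.0108 with both removed, with or without a block. Bortezomib genes (566) were 288 with a pseudocount of 5, which shrinks ratios, and 1003 with a minimum FPKM of 1 or none; 8 lists outside the random range (3 above, 5 below) were 9 at a pseudocount of 0.1 (4 above) and 9 without matching on level (1 above, 8 below), where oxidative phosphorylation and early B-lineage were inside and G1/S, ribosomal protein and erythroid genes outside. The correlation of 0.509 between both exosome contrasts was 0.615, and that of -0.014 with bortezomib -0.038, at a pseudocount of 0.1. Leaving out a library lowers the residual degrees of freedom from 2 and assumes the lone library varies like the others; for the other shifts the cause was not tested. Alternatives conditional on counts were not run, since counts were not used here. Depth limits statements on genes under an FPKM of about 1, most in the bortezomib table (10000000 fragments).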

Other observations

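The genes shown here were chosen after their values were seen, and no explanation is offered for them. Several of the largest bortezomib differences had the exosome-table libraries near the bortezomib level rather than the DMSO level, although the tables were normalized separately. SOCS2 stood at 180.37 FPKM with DMSO, 2.56 with bortezomib and 3.66 in the untreated library. DNTT stood at 136.6, 4.35 and 8.79, BLNK at 60.5, 1.63 and 5.30, and VAMP8 at 0.80, 48.89 and 137.06 in the same order. HOXA9 stood nearer DMSO, at 34.82 in the untreated library and 34.03 and 34.22 after Nexo. Of 59 genes at least 4-fold lower with bortezomib and measured in both tables, 39 lay nearer DMSO in all 5 exosome-table libraries and 15 nearer bortezomib, and of 43 at least 4-fold higher, 18 lay nearer DMSO and 22 nearer bortezomib.

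Other B-cell, chromatin and metabolic genes were far apart with bortezomib. CD52, a surface antigen of lymphocytes, stood at 27 FPKM with DMSO and 276.62 with bortezomib, and the histone deacetylase HDAC9 at 5.19 and 63.18. TCL1A, a kinase coactivator of B cells, stood at 131.48 and 12.36, and the p53 target SESN1 at 37.84 and 3.31. The carbonyl reductase CBR1 (10.24 with DMSO) and the pyruvate dehydrogenase kinase PDK2 (12.8) were listed at 0 with bortezomib, against 8.33 and 8.73 in the untreated library. MIR6723 had 13657.63 and 11441.90 FPKM in the DMSO and bortezomib libraries and 5999.69 in the untreated library, in tables from which mitochondrially encoded genes were absent.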
